A study of Homo sapiens with 3 samples.

How the data were processed

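MicroRNAs were measured in MCF12A cells, an immortalized, non-tumorigenic human mammary epithelial line, on 1-colour microarrays of a commercial service. Per the labels' protocols, each assay used 2 µg of total RNA, a poly(A) tail was added to the RNA 3' ends, and a tag on that tail was stained with the dye Cy5. The labels gave 3 groups of 1 array each: unexposed control cells, cells exposed to ethanol for 4 weeks and cells exposed to acetaldehyde for 4 weeks. The treatment protocol also describes a clone grown in soft agar, which the labels assign to none of these arrays. The groups had no replicate, so no p-value and no replicate SD could be computed, and nothing below has a replicate check.

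The per-array files held the median intensity of each spot as deposited, with no background column and, per the file headers and the level of the empty spots, no background subtraction or normalization. Each array carried 2019 human microRNA probes with 4 spots each, 2 in each of 2 blocks at the same places on every array, together with 1368 empty spots, spike calibration spots and 5S ribosomal RNA spots. The scanner, the image software and the release of the microRNA database are not given in the sources used here. The deposited series table held 1 linear intensity per probe and array, normalized between arrays by the authors with a method not given in the sources used here. Its column medians were 26.9, 29.2 and 26.2 for the control, ethanol and acetaldehyde arrays. Set against the per-array files, its log2 values correlated at r of 0.999, 0.999 and 0.998 over 304, 242 and 333 probes well above the empty spots. The ratio of the deposited value to the net spot value differed between arrays: its median among dim and among bright probes of that set was 0.884 and 0.895 on the control array, 1.37 and 1.12 on the ethanol array, and 0.857 and 0.993 on the acetaldehyde array. That table was used as an alternative.

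Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, fitted on all spots. Values were then taken to log2, the 4 spots of a probe were averaged, and the 3 arrays were quantile normalized over the 2019 microRNA probes. Before normalization the median of all probes lay 0.31 higher on the acetaldehyde array than on the control array, and on the ethanol array it differed by -0.13 (log2). Quantile normalization moved each intensity range by its own amount, so those medians, set mostly by dim probes, are not a constant to add back. With acetaldehyde, for example, miR-203a differed from control by 1.07 with normalization and by 0.81 without. Further steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. The error given with a log2 difference is the SD over the 4 spot positions (n = 4 spots on 1 array per group). It measures printing and reading of spots, not variation between cultures.

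A probe was called detected when its mean spot intensity exceeded the median of the empty spots by 3 of their SDs, with at least 50% of its spots above that level. Differences were described by size: at least 2-fold among probes detected on both arrays. A microRNA was named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest differences per comparison among detected microRNAs with a normalized intensity of at least 500 on 1 of the arrays, where these reached 2-fold. It also took up to 5 per direction that were detected on 1 array only with at least 500 there. In each of 26 fixed lists it took the 2 brightest members and the member with the largest difference, of which the report prints a part, and it added the 5 brightest microRNAs of the control array. A microRNA detected on 1 array only is given as at least N-fold, its level there against the higher of the lowest detected signal on the dim array and its own signal.

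The lists covered microRNA families and clusters, breast cancer, p53 and ethanol related microRNAs, markers of epithelium and of other cell types, entries overlapping other small RNAs, and GC-rich entries. A list was read as the median log2 difference of its members detected on both arrays. Where at least 3 members were detected, its percentile among 10000 random lists of the same size, matched on mean intensity in 10 bins, is given as a description of these arrays. Where several probes carried a member's name, the brightest over the 3 arrays was used. The arm was thus picked by brightness, not by known function. Picked arms included miR-34c-3p of the p53 list, and miR-143-5p, miR-142-5p and miR-150-3p of the cell type markers. A list value holds for the picked arms only. Names are those of the array design. The files give no genome positions, and none were used here.

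A spot was called dark when its net signal was under 50% of the median of its probe's 4 spots, for probes with a median net signal over 300. There were 13 such spots, 3 on the control array, 6 on the ethanol array and 4 on the acetaldehyde array. Leaving them out, and the other alternatives of background correction, normalization, detection, spot summary and size threshold, were computed as alternatives. The steps were tested on simulated data made from the control array, with known changes given to part of the probes, for acetaldehyde against control over 2019 probes. Of changes of 2.5-fold, 96.7% were called at control intensities of at least 500 and 19.6% below. Of changes of 4-fold, 94.1% and 83.3% were called, and 0 of 563 unchanged detected probes were called. Over the 720 detected simulated probes, a list of 9 raised probes lay at percentile 99.9, and 2.0% of lists of 9 unchanged probes lay outside the central 95% of random lists. The simulated array kept the probe means and empty-spot level of the control array and added noise between spots only. These rates therefore leave out differences between arrays and between cultures. The median size of difference was 0.069 (log2) for unchanged simulated probes, against 0.29 for all microRNAs detected on the real control and acetaldehyde arrays.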

Results

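The series profiled microRNAs in MCF12A breast epithelial cells kept for 4 weeks with ethanol or with acetaldehyde, the first oxidation product of ethanol, beside unexposed cells. There was 1 array per group, and the comparisons of ethanol and of acetaldehyde with control share the single control array. The labels disagree on the doses: the sample characteristics state 2.5 mM ethanol and 1 mM acetaldehyde, and the treatment protocol states 2.5% and 1%. The ethanol and acetaldehyde doses differ on either reading. The number of arrays limits the precision of every value.

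The brightest probe of the control array was miR-205-5p, a microRNA of basal epithelial cells, at a normalized intensity of 22121 (log2 14.43), followed by miR-21-5p, abundant in many cultured and tumour cells, at 16567. Next came miR-23b-3p at 16336, miR-23a-3p at 16053 and let-7a-5p at 14255. miR-205-5p and miR-21-5p held the highest ranks on all 3 arrays, so quantile normalization gave each the same value there. The number of detected microRNAs was 775 on the control array, 347 on the ethanol array and 1430 on the acetaldehyde array, out of 2019. The empty spots had medians of 106, 148 and 65.8 and SDs of 13.6, 31.6 and 10.97 in the same order, so the level a probe had to exceed was 146, 243 and 98.8. The summed signal above the empty spots was 877255, 703875 and 865942. All 347 microRNAs detected on the ethanol array were also detected on the other 2.

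With ethanol, most detected microRNAs were close to control: 305 of 347 (87.9%) lay within 1.5-fold. Leading the higher side were miR-4668-5p, 2.56-fold above control (log2 difference 1.36 ± 0.20, SD over 4 spot positions), and miR-155-5p, a microRNA of immune and inflammatory signalling that is raised in many breast tumours, 2.01-fold above control (1.01 ± 0.12). Without normalization miR-155-5p stood at 0.70, short of 2-fold, and miR-4668-5p at 1.01. miR-3613-3p, named after its values were seen, stood 0.93 ± 0.20 above control. let-7 microRNAs, which restrain RAS and HMGA2 expression, were near control, with a family median of -0.02 over 9 members and miR-98-5p as the exception at 0.64 (dark spots left out). Over the alternatives that median ranged from -0.10 to 0.32.

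In all, 3 microRNAs were at least 2-fold higher on the ethanol array and 1 was at least 2-fold lower. The remaining higher one, miR-19b-3p, read 1.49 ± 2.27, but 1 of its 4 control spots was dark (166 against a probe median of 3850). Without that spot the difference was 0.27. The lower one was miR-4454 at -1.06 ± 1.11, which became -0.61 without a dark spot on the ethanol array. let-7f-5p, at 0.99 ± 1.84, also held a dark control spot and came to -0.02 without it. Without normalization the counts were 2 higher and 9 lower, and with scaling on the median of detected microRNAs 5 higher and 0 lower. These counts cover probes detected on both arrays. They leave out miR-4521, detected on the control array (log2 8.87) and not on the ethanol array (7.41). Its control intensity of 469 also kept it outside the naming rule for ethanol against control.

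The GC-rich high-numbered entries formed the list that stood highest on the ethanol array. Their median was 0.31 over 27 detected members, above all 10000 random lists, and 18 of the 27 were higher at all 4 spot positions, as were 110 of all 347 microRNAs. The median was 0.086 without normalization and 0.51 with scaling on the median of detected microRNAs, and a model of base content, length and A runs left 0.13 (SE 0.072). Examples are miR-3960 at 0.31 ± 0.16, miR-6089 at 0.13 ± 0.13 and miR-4532 at 0.85 ± 0.17. Across the 347 microRNAs the difference was higher for targets of higher G content (Spearman rho 0.31, across probes, which are not independent replicates). Entries overlapping tRNA, snRNA, rRNA or vault RNA had a median of -0.41 over 5 members, at percentile 1.37. That list included miR-4454 and miR-1260a with dark spots, and its median was -0.28, at percentile 7.60, without them.

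The remaining lists lay within the central 95% of random lists on the ethanol array in the main setting. The miR-15/16 family, which targets cell cycle genes, had a median of -0.34 over 5 members at percentile 3.88 (-0.36, at percentile 1.84 and so outside, without dark spots), with miR-16-5p at -0.40 ± 0.06 and miR-15a-5p at -0.41 ± 0.13. The miR-23/27/24 clusters had a median of -0.34, with miR-27b-3p at -0.44 ± 0.06, and the miR-183 cluster one of -0.34, with miR-182-5p at -0.34 ± 0.08. Medians were -0.22 for the miR-200 family, which holds epithelial identity by repressing ZEB factors, -0.17 for miR-17/92 and its paralogs, -0.13 for the miR-30 family and -0.19 for the miR-181 family. miR-181c-5p was the lowest of that family at -0.80 ± 0.20. These medians move with the scaling: over the alternatives the miR-23/27/24 median ranged from -0.42 to 0.094 and the miR-17/92 median from -0.40 to 0.024. Among microRNAs linked to ethanol in other tissues, 4 were detected, with a median of 0.00 (0.17 without dark spots). miR-155-5p was higher, as given above, miR-21-5p did not differ in rank, and miR-34a-5p read 0.09 without its dark spot.

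With acetaldehyde, the let-7 family was lower than on the control array. let-7c stood at -1.58 ± 0.36, let-7e-5p 2.66-fold below control (-1.41 ± 0.29), let-7b-5p 2.36-fold (-1.24 ± 0.17), miR-98-5p 2.24-fold (-1.17 ± 0.21), let-7d-5p 2.09-fold (-1.07 ± 0.20) and let-7a-5p -1.06 ± 0.16. The members let-7i-5p (-0.69) and let-7g-5p (-0.38) were lower by less. On the higher side stood miR-203a, which acts in keratinocyte differentiation by repressing p63, at 2.10-fold (1.07 ± 0.15), and both arms of the basal epithelial microRNA miR-31, with miR-31-5p at 2.03-fold (1.02 ± 0.12) and miR-31-3p at 2.13-fold (1.09 ± 0.09). Without normalization these 3 fell short of 2-fold, at 0.81, 0.81 and 0.92.

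The let-7 family median was -1.07 over 9 members and lay below all 10000 random lists. Of the 9 members, 6 were at least 2-fold lower, and 8 were lower at all 4 spot positions, as were 282 of all 774 microRNAs. The exception was let-7f-5p at -0.02, a value set by its dark control spot. It came to -1.01 without that spot, and 7 members were then at least 2-fold lower. The family median lay between -1.36 and -1.03 over the alternative settings, and at single spot positions it reached -0.97. Members differ from let-7c by 1 to 4 of 22 bases, so a probe may read its neighbours and the members are not independent.

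**Figure D1:**
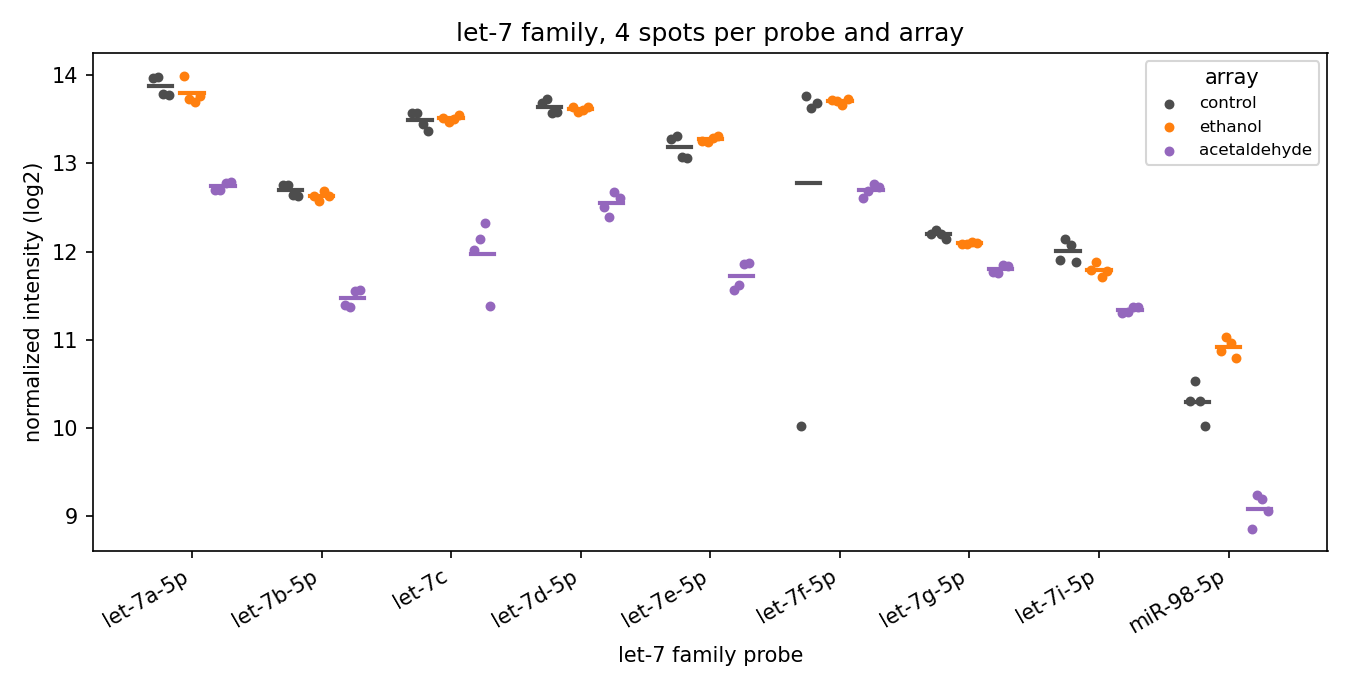
Normalized log2 intensity of the let-7 family probes, 4 spots per probe (points) with their mean (bar), on the control, ethanol and acetaldehyde arrays. The control and ethanol spots of let-7a-5p lie about 1 log2 unit above its acetaldehyde spots, and the single low control spot of let-7f-5p is the dark spot described in the text.

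In all, 8 microRNAs were at least 2-fold higher and 14 at least 2-fold lower on the acetaldehyde array, out of 774 detected on both, and 651 (84.1%) lay within 1.5-fold. Of the 774, 242 had an intensity of at least 500 on 1 of the arrays. Differences of dim probes read small: simulated 2.5-fold changes had a median of 0.75 (log2) below 500 and 1.24 above. The share is therefore not comparable with that of the 347 microRNAs with ethanol. Further bright ones on the higher side were miR-5096 at 1.41 ± 0.21, miR-4521 at 1.07 ± 0.09 and miR-99a-5p, which represses mTOR, at 1.03 ± 0.28. Without normalization miR-5096 stayed above 2-fold (1.06), and miR-4521 (0.83) and miR-99a-5p (0.69) did not. miR-19b-3p read 1.82 ± 2.09 and 0.62 without the dark control spot. The lowest of all was miR-4764-3p at -1.68 ± 0.62, and miR-1973, miR-4651, miR-1587 and miR-4481 lay between -1.18 and -1.07, of which miR-1973 and miR-1587 fell short of 2-fold with scaling on the median. That scaling gave 63 higher and 10 lower, and no normalization 6 higher and 19 lower, so the balance of directions depends on the scaling.

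Against the let-7 family stood 2 groups that were higher on the acetaldehyde array. The miR-17/92 cluster and its paralogs, which MYC induces and which promote proliferation, had a median of 0.56 over 12 members at percentile 99.9, and 10 of them were higher at all 4 spot positions, as were 208 of all 774 microRNAs. miR-20a-5p stood at 0.44 ± 0.13, and miR-92a-3p was the exception at -0.22 ± 0.10. The miR-30 family had a median of 0.65 over 5 members at percentile 99.1, all of them higher at all 4 positions, with miR-30e-5p at 0.79 ± 0.15 and miR-30b-5p at 0.52 ± 0.11. Without normalization its median was 0.32 at percentile 93.0. Several members of each group have closely related sequences. The direction of both groups is relative to the other microRNA probes, since no alternative was scaled on control probes. Before normalization all spike probes except a2-PUC2PM-20B and a3-PUC2PM-20B were also brighter on the acetaldehyde array, by up to 1.56. The 5S ribosomal RNA probes shifted the other way, by a median of -0.16. The spikes could thus place both groups lower, and the 5S probes higher.

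Entries overlapping tRNA, snRNA, rRNA or vault RNA were lower, with a median of -0.60 over 6 members at percentile 0.525, all lower at all 4 positions. miR-1973 was the lowest at -1.18 ± 0.18, and miR-1260b stood at -0.63 ± 0.32. Other lists lay within the central 95% in the main setting. Medians were 0.52 for the miR-23/27/24 clusters, with miR-24-3p at 0.66 ± 0.08, 0.46 for the miR-99/100 and miR-125 families, with miR-125b-5p at 0.86 ± 0.16 and miR-125a-5p at -0.09 ± 0.15, and 0.36 for the miR-29 family, with miR-29c-3p at 0.81 ± 0.40. The 2 members of the miR-221 cluster stood at 0.23 ± 0.41 (miR-221-3p, with a dark spot) and 0.60 ± 0.03 (miR-222-3p), and the miR-26 family had a median of 0.35 over 2 members, with miR-26a-5p at 0.59 ± 0.08. The miR-15/16 and miR-181 families had medians of 0.11 and 0.13, with miR-15b-5p at -0.16 ± 0.18, and the GC-rich entries one of -0.15.

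MicroRNAs that promote breast cancer had a median of 0.21 over 10 members on the acetaldehyde array (0.32 without dark spots, 0.12 to 0.55 over the alternatives), with miR-27a-3p at 0.57 ± 0.08 and miR-96-5p at 0.80 ± 0.21. Of the 10, 6 were above 0 and 3 below, the lowest being miR-155-5p at -0.35. miR-183-5p, of the same cluster as miR-96-5p, was lower, at -0.82 ± 0.13, and miR-182-5p stood at 0.19 ± 0.16. Those that restrain it had a median of 0.19 over 10 members (0.12 to 0.43 over the alternatives), with miR-31-5p and miR-125b-5p as given above. The p53-induced microRNAs had a median of 0.34 over 7 members (0.24 to 0.82), with miR-194-5p at 0.98 ± 0.28 and miR-107 at 0.63 ± 0.10. Of the 7, 5 were above 0 and 2 below, miR-34b-3p and, as the lowest at -0.16, miR-34c-3p. With ethanol the median of that list was -0.02 over 6 members (0.06 without dark spots). The epithelial and basal mammary markers had a median of 0.23 over 9 members, set by miR-221-3p with its dark spot. It was 0.43 without dark spots and ranged from 0.097 to 0.68 over the alternatives. Within the miR-200 family, miR-141-3p was higher at all 4 spot positions (0.71 ± 0.13), with miR-200c-3p at -0.12 ± 0.07 and miR-200b-3p at -0.29 ± 0.34.

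Set beside each other, the exposures differ in compound and in dose. miR-203a was 2.96-fold higher on the acetaldehyde array than on the ethanol array (1.57 ± 0.25), and miR-23c 2.51-fold (1.33 ± 0.14). miR-31-3p (2.38-fold), miR-181c-5p (1.21 ± 0.12), miR-96-5p, which represses FOXO factors (1.14 ± 0.05), miR-135b-5p (1.08 ± 0.23) and miR-29c-3p (1.04 ± 0.17) were also higher. Lower were miR-4668-5p at 3.59-fold (-1.84 ± 0.25), miR-98-5p at 3.45-fold (-1.79 ± 0.12), let-7c (-1.58 ± 0.44), let-7e-5p (-1.50 ± 0.13) and miR-155-5p (-1.35 ± 0.24). miR-1973 (-1.28 ± 0.25), miR-612 (-1.19 ± 0.19) and let-7b-5p (-1.15 ± 0.08) were lower as well. Without normalization miR-29c-3p (0.89) and miR-612 (-0.80) fell short of 2-fold, and so did miR-135b-5p with cyclic loess. miR-183-5p, of the miR-96 cluster, was lower than with ethanol (-0.76 ± 0.08). miR-4521 was detected on the acetaldehyde array and not on the ethanol array, at least 3.64-fold higher, and so was miR-3065-5p, at least 2.14-fold higher. Part of the miR-4521 gap lay on the ethanol side. Its log2 intensity was 8.87 on the control array, 7.41 on the ethanol array and 9.94 on the acetaldehyde array.

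Of 347 microRNAs detected on both, 7 were at least 2-fold higher and 15 at least 2-fold lower with acetaldehyde. Without normalization the counts were 14 and 12. The let-7 family median was -1.04, below all random lists, with all 9 members lower at all 4 positions, as were 149 of the 347. The miR-17/92 list stood at 0.66, above percentile 99.9 of random lists, with all 12 members higher at all 4 positions, as were 108 of the 347. The p53-induced list stood at 0.53 (percentile 99.9), and the list of microRNAs that restrain breast cancer at 0.44, outside the central 95%, which became 0.15, at percentile 78.5, without dark spots. Without them the list of microRNAs that promote breast cancer lay outside instead, at 0.50 and percentile 98.5, against 0.40 with them. The GC-rich entries had a median of -0.45 at percentile 0.305, with miR-1908 at -1.10 ± 0.18 and miR-4497 at -1.04 ± 0.16 (miR-1908 at -0.88 without normalization), and across microRNAs the difference was lower for targets of higher G content (rho -0.47).

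**Figure D2:**
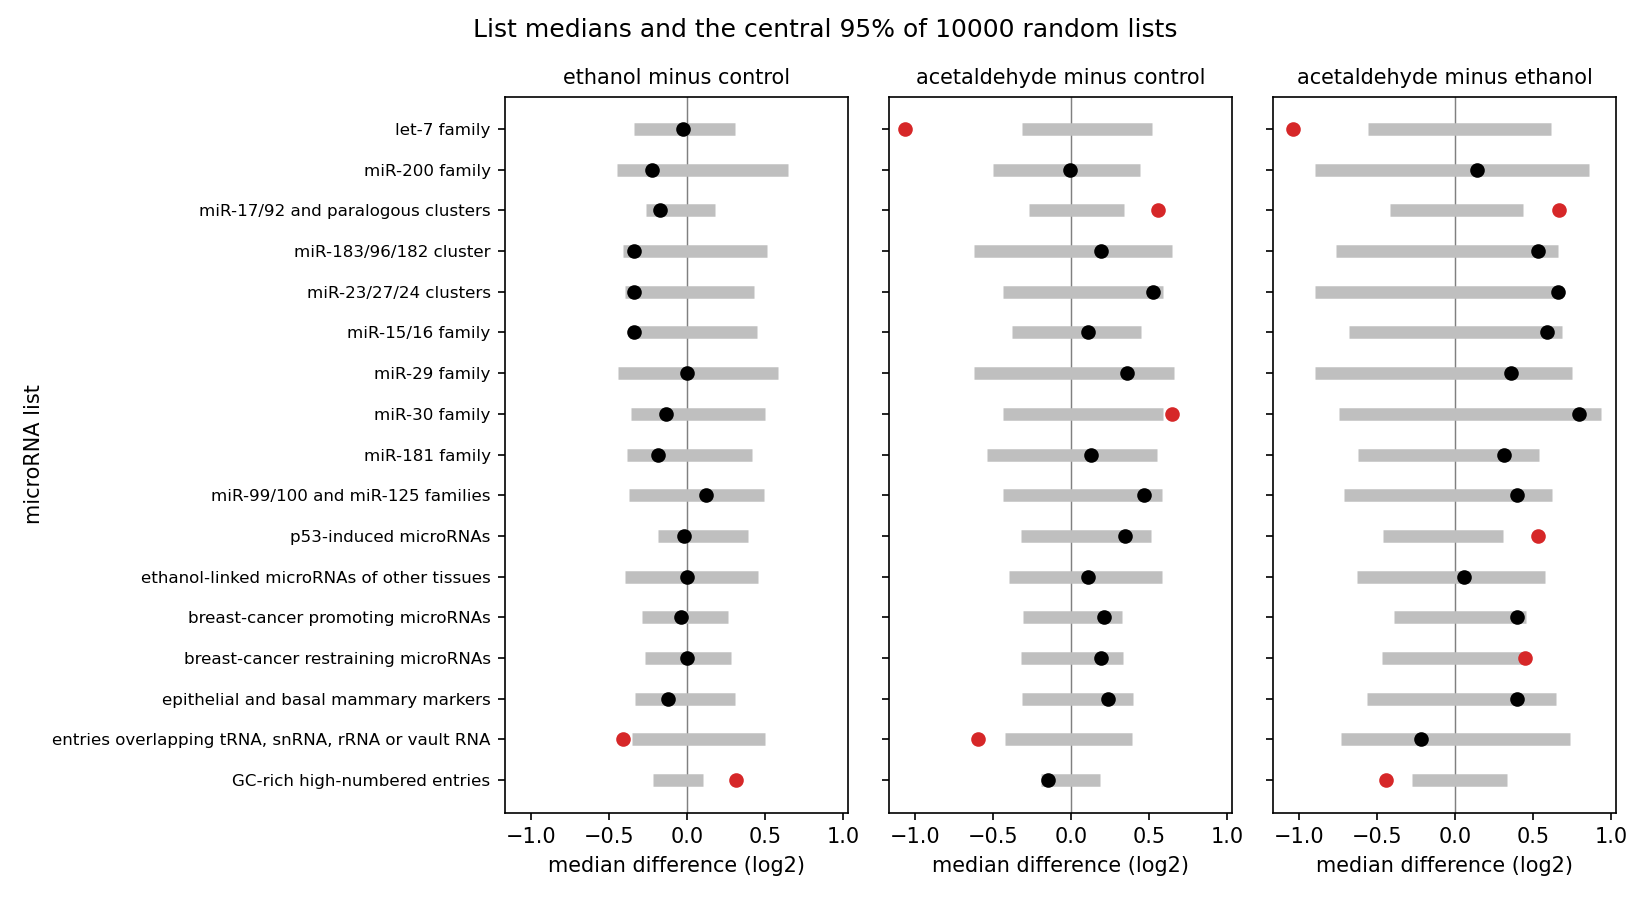
Median log2 difference of each fixed microRNA list with at least 3 detected members (points) and the central 95% of 10000 intensity-matched random lists (grey bars), for the 3 comparisons. Red points lie outside the grey bar or on its end: the let-7 family lies at -1.07 for acetaldehyde against control and at -0.02 for ethanol against control, inside its bar.

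Across the 347 microRNAs detected on all 3 arrays, Pearson's r was 0.18 and Spearman's rho 0.15, over probes that are not independent replicates. Leaving out the 2 microRNAs farthest from the median on the ethanol axis gave r of 0.15. A shared control alone gave r of 0.50 in simulations of 3 arrays with independent noise of the observed size and the same variance on each array. The SD of the differences was 0.38 for ethanol against control and 0.57 for acetaldehyde against ethanol. Equal variance therefore need not hold, and 0.50 is not a firm expectation for these arrays. The covariance was 0.033, against 0.12 in those simulations and 0.013 in simulations of the noise between spots. With the control spots split by block, so that each exposure was set against other spots of the same array, r was 0.11 and 0.043. Of the microRNAs at least 2-fold higher, 3 with ethanol and 6 with acetaldehyde, 1 was shared, miR-19b-3p, whose dark control spot enters both differences. Independent lists would share 0.052. The single lower microRNA with ethanol is too few for an overlap to be read.

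**Figure D3:**
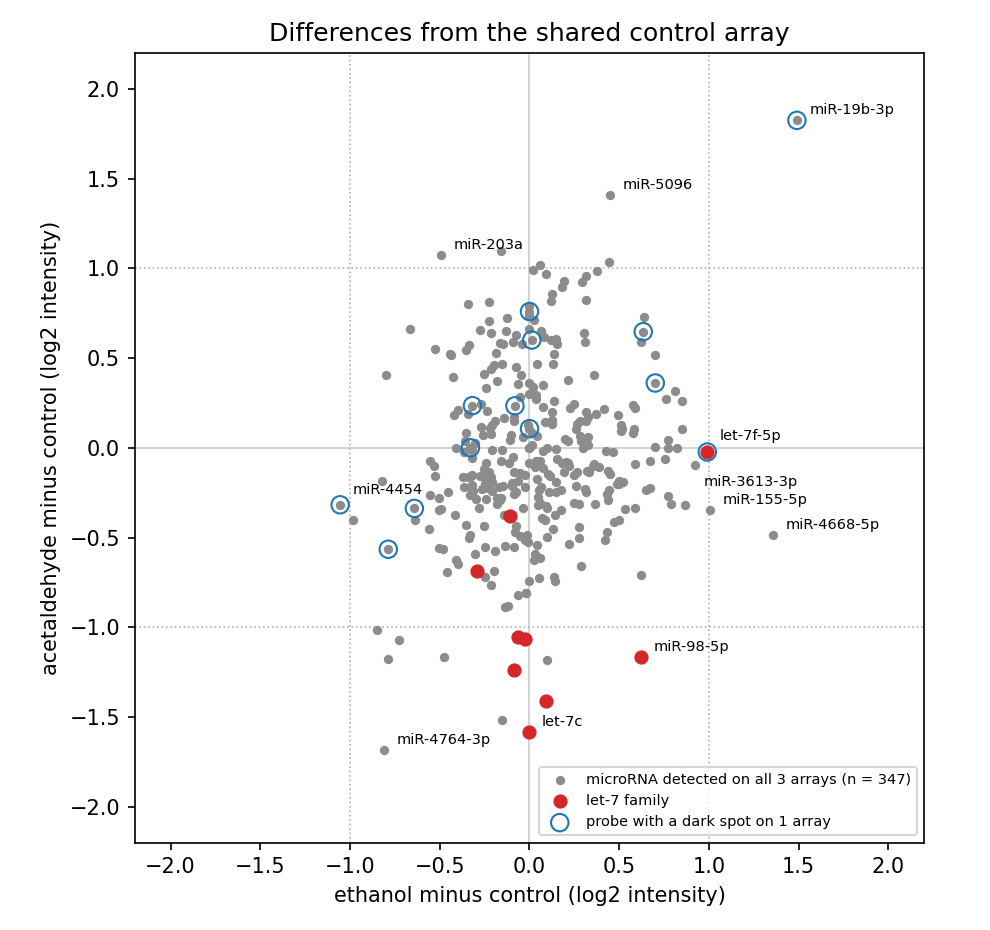
Log2 difference from the control array with ethanol (horizontal) and acetaldehyde (vertical) for 347 microRNAs detected on all 3 arrays. Red points are the let-7 family, circles mark probes with a dark spot on 1 array, and dotted lines mark 2-fold. The correlation is 0.18, and let-7c lies at -1.58 on the vertical axis.

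Among markers of other cell types, of 7 mesenchymal and fibroblast markers, 3 were detected on the control array, 2 on the ethanol array and 7 on the acetaldehyde array, which had the lowest detection level. For the liver marker miR-122 the probe used was miR-122-3p, the brightest with that name, and it was detected on none of the 3 arrays. Of the blood cell and serum markers only miR-16-5p, which most cells express, and the dim miR-150-3p were detected on all 3 arrays. The mesenchymal and fibroblast markers miR-10b-5p and miR-214-3p differed from control by 0.06 ± 0.30 and -0.18 ± 0.20 with ethanol, and by -0.08 ± 0.30 and -0.31 ± 0.25 with acetaldehyde. The endothelial marker miR-126-3p stood at 0.19 ± 0.09 with ethanol and 0.93 ± 0.09 with acetaldehyde, where its log2 intensity was 9.51. The muscle marker miR-206 stood at 0.26 ± 0.21 and -0.21 ± 0.28, the neural marker miR-128 at -0.25 ± 0.09 and -0.13 ± 0.30, and miR-371a-5p of the pluripotency and placenta clusters at 0.25 ± 0.16 and -0.31 ± 0.23.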

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

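The tests of spike probe gaps below were chosen only after their values were seen. Spike calibration probes, which no comparison used, were brighter on the acetaldehyde array than on the control array by 2-fold or more in 6 cases (log2, background-corrected, not normalized between arrays). They were a2-PUC2MM-20B at 1.56, a-PUC2MM2d at 1.49, Ctr06-3M10 at 1.28, Ctr06-3P at 1.17, a3-PUC2MM-20B at 1.15 and Ctr06-3M05 at 1.08. The other spike probes were brighter there by less than 2-fold, except a2-PUC2PM-20B and a3-PUC2PM-20B, which were dimmer (-0.33 each). The median shift of all microRNA probes was 0.31, and the 5S ribosomal RNA probes shifted by a median of -0.16. No spike probe was brighter by 2-fold on the ethanol array, and 1 was dimmer there by that much, Ctr09-3M05 at -1.12.

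These spikes bear on the number of detected microRNAs, 1430 on the acetaldehyde array against 775 on the control array. The deposited table gave 929 against 931 at 32 units. Its normalization between arrays levels counts at a fixed cut-off, so those counts cannot tell whether the excess is real. The level of the empty spots could set the count, and with 1 cut-off above them on every array the acetaldehyde count was 1.54 times the control count (773 against 501; above 1000 units 147 against 165). With an SD of 0.16 over the 4 spot positions, that passes the bound of 1.5 set for ruling it out by less than the SD, so it stays open. Weaker discrimination of mismatched sequences could also raise dim probes: the gap between spike probes named PM and MM was smaller on the acetaldehyde array in 5 of 5 pairs, with changes from -0.050 (PUC2) to -1.89 (a2). In the a2 and a3 pairs the very bright PM probe was also dimmer there, which adds to the change of the gap. Among the 11 sets named 3P, 3M05 and 3M10, names not explained in the sources used here, the 3P probe shifted up more than both 3M probes in 7 and less than both in 3, so that explanation stays open too, and a biological gain of dim microRNAs stays untested.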

How the results depend on the processing

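Restrictions to 1 block, omission of dark spots and detection from local background were chosen after seeing the data, and the cause of the changes below was not tested. Counts are microRNAs at least 2-fold higher and lower. For ethanol against control (main counts 3 and 1), plain background subtraction gave 13 and 3, scaling on the median and cyclic loess each 5 and 0, block 1 alone 7 and 2, and block 2 alone 1 and 2. Lower counts were 2 with normexp offset 16, quantile over detected microRNAs or no detection filter, 9 without normalization, and 0 with spot medians, the deposited table, spot variation under 0.5 or dark spots left out. For acetaldehyde against control (8 and 14), plain subtraction gave 102 and 146, offset 16 gave 15 higher and median scaling 63 higher. For acetaldehyde against ethanol (7 and 15), plain subtraction gave 13 and 45, and the higher count was 14 without normalization, 12 without a detection filter, 4 with detection at 6 SDs and 11 in block 2 alone. A 1.5-fold threshold gave 30 and 12, 60 and 63, and 51 and 62 in these comparisons, and a 3-fold threshold 0 and 0, 1 and 1, and 0 and 2. The let-7 median with acetaldehyde (-1.07) was -1.36 without normalization and -1.24 in the deposited table, and from -1.21 to -1.03 under the other alternatives. The deposited table, at 32 units, gave 931 detected microRNAs on the control array, 966 on the ethanol array and 929 on the acetaldehyde array. Lists outside the central 95% of random lists with ethanol numbered 2, and 1 without normalization, with median scaling, cyclic loess, spot medians, the deposited table, an intensity of at least 500, spot variation under 0.5 or local detection. For acetaldehyde against ethanol there were 5, counting the list that lay on the bound, and 3 with an intensity of at least 500 or detection at 6 SDs. The median of entries overlapping other small RNAs with ethanol turned from -0.41 to 0.096 with spot variation under 0.5, where 3 members remained. The correlation of the exposures stayed between 0.078 and 0.32. Dim probes limit these arrays: below an intensity of 500 most simulated 2.5-fold changes were missed. No paired analysis was possible because each group holds 1 array.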

Other observations

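The tests of normalization and of spot position for let-7, and both tests for the A-run probes, were chosen after the result was seen. The tests of composition, of sequence distance and of hairpin arms were written before. The omission of dark spots in the tests of distance and of arms was chosen after the data were seen. The microRNAs miR-192-5p and miR-194-5p, which share a cluster and which p53 induces, were brightest on the acetaldehyde array: miR-194-5p had log2 intensities of 7.78, 8.15 and 8.76 and miR-192-5p 7.85, 8.16 and 8.67 on the control, ethanol and acetaldehyde arrays. miR-196a-5p, a HOX cluster microRNA too dim for the naming rule and chosen after its values were seen, was lower with acetaldehyde (-1.52 ± 0.15), by a size that depends on background handling and scaling (-4.06 to -1.08 over the alternatives).

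The lower let-7 family on the acetaldehyde array was weighed against 4 technical explanations. Normalization would have to make the difference, and over 5 other scalings the family median was at most -1.05. A model of base content, length and A runs left a median residual of -0.75 (SE 0.17) of the -1.07. Composition as modelled thus accounts for a part of the difference only. The model explained 15.3% of the variance and the SE counts related members as independent, so effects of sequence outside the model are not ruled out. The median was at or below -0.97 at each of the 4 spot positions, so a damaged region does not account for it. Cross-hybridization stays open: the rank correlation of sequence distance from let-7c with the difference was 0.68 over 8 members other than let-7c without dark spots and 0.40 with all spots. With let-7c counted it was 0.78 over 9 members without dark spots, a value raised by let-7c having been picked as the most changed. A drop in few members may thus have spread to the probes of the rest. A change of the family in the exposed cells is a further hypothesis, and 1 array per group cannot tell it from a difference between cultures.

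miR-4668-5p and miR-3613-3p, brighter on the ethanol array, are the only microRNAs on the array whose targets hold a run of 10 A bases. Damaged spots do not account for the pattern, since the smallest difference at any spot position was 0.69. Since the assay adds a poly(A) tail, such probes might capture tails rather than the microRNAs. The 3 detected probes for runs of 5 or 6 bases had a median difference of 0.035 and A-run length showed no increasing trend (rho -0.15). That meets the bound written for ruling capture out, but no detected probe covers runs of 7 to 9 bases, so capture of tails by long runs cannot be told apart from a change of both microRNAs.

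If the amount of a shared precursor changed, the arms of 1 hairpin would shift together. With ethanol the rank correlation of the arms was -0.094 over 18 hairpins, below what random pairings reach at their 90th percentile (0.31) by more than its SE of 0.24. That meets the bound written against a shared change, for these 18 hairpins. With acetaldehyde the correlation was 0.110 over 119 hairpins, at percentile 89.1 of random pairings. It also lay under their 90th percentile (0.115), but by less than its SE of 0.092, so the bound does not settle it. After removal of the composition trend it was 0.31, at percentile 99.9, a measure added after the test was written. The hypothesis stays open for acetaldehyde.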
